A study of Drosophila melanogaster with 2 samples.

How the data were processed

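Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on whole embryos of a transgenic Drosophila melanogaster strain that carries the homeodomain transcription factor H2.0 fused to enhanced green fluorescent protein (eGFP). Per the labels, the immunoprecipitation used an antibody against GFP, the embryos were 0 to 24 h old, chromatin was sheared by sonication, and fragments of 200 to 800 bp were taken. The labels give 1 group of 2 biological replicates and no second condition. The group and the replicate numbers were taken from the labels.

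Peak lists were used here and no reads, so the depth of each library is unknown and no interval that needs it is given. The lists were made per replicate and for both replicates together, each in a ranked and a thresholded form, and a conservative thresholded list stood beside the series-wide one. Coordinates are on build dm6, per the labels. The deposited signal value of a peak is the peak caller's enrichment signal, per the labels' file listings and the narrowPeak column order, and is not scaled between lists, so it was used to rank, split or describe peaks within a list, and between the replicates only in rank correlations and in the SD of log2 ratios, which a common factor leaves as they are. The deposited score is the irreproducible discovery rate (IDR) score, scaled by the authors to an upper limit, and every thresholded list held scores of 830 or more, which corresponds to an IDR of 0.01. The deposited lists also give −log10 of a q-value for each peak and, in the ranked lists, −log10 of the global IDR. Both of these were used as the authors gave them. The peak caller, the aligner and their versions are not given in the sources used here. The ranked list of both replicates also carries 2 signal values per peak, which were identified as those of the 2 replicates because their component peaks occur with the same interval and signal in the per-replicate ranked lists. Which of the 2 columns belongs to which replicate carries no label and was not assigned here, so the comparisons reported from these columns are without an order. The thresholded lists were derived from 1 further file besides the alignments, per the labels' file listings, and leave out some ranked peaks past the score. The control library named in the labels was not used here.

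The main peak set was the series-wide thresholded list that is not the conservative one. Summits on the arms 2L, 2R, 3L, 3R, 4, X and Y were placed on the Ensembl annotation of the matching assembly (18277 genes other than transposable elements, 13968 of them protein-coding). Arm lengths of the reference sequence and of dm6 were compared before coordinates were used. Peaks were called shared when their summits lay within 200 bp. A promoter summit lay within 500 bp of any annotated transcription start site (TSS), and other summits were classed in the order 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Overlaps and class shares were tested against 1000 circular shifts of the summits along each arm, two-sided, with Benjamini-Hochberg adjustment over the classes. Promoter and other signal values were compared by a two-sided permutation test with 100000 resamples.

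A gene counted as covered when a main-set summit lay in its span widened by 1 kb on both sides. Each of 19 gene lists was tested against 10000 random lists of protein-coding genes matched on span length in 20 bins, two-sided, with Benjamini-Hochberg adjustment over the lists. Sequence within 50 bp of each summit was searched on both strands for 17 fixed motifs and for all 6-mers, a 6-mer and its reverse complement being counted together. The background was a window of the same width centred 400 bp to one side of the same summit, the side drawn with a fixed seed (anew for each other peak list, except the stronger part of the main set), and the exact McNemar test (two-sided) with Benjamini-Hochberg adjustment was used. The odds are the windows with the sequence at the summit only over those with it in the background only, with 0.5 added to both counts. No binding matrix of H2.0 was used. Tests over peaks or genes describe these lists, since peaks and genes are not independent replicates.

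The gene lists, the motifs, the tests, the first group of alternatives below and the rule for named genes were fixed before the data were examined. The rule took H2.0, the gene with the nearest TSS for each of the 25 highest-signal main-set peaks with a summit within 200 bp in both per-replicate lists, up to 4 members of each gene list with the highest signal, every fixed motif past an adjusted p of 0.05, and the 5 6-mers with the largest odds in each direction. The alternatives fixed beforehand were the conservative list, each replicate's own list, the stronger part of the main set by signal, other distances for shared peaks, promoters and gene assignment, wider motif windows, random genome windows matched on GC content, and other IDR thresholds. Alternatives chosen after seeing the data left out shoulder peaks (peaks that share a component peak with a stronger one), added the ranked peaks that the thresholded list leaves out, drew the flank side 200 more times for the main set, left out shoulder peaks with each other summit keeping its flank, or used 128022 weak ranked peaks as the background for genomic classes.

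The tests were tried on simulated data. For promoter share, 3 of 40 shifted copies of the 4565 summits passed 0.05, and 40 of 40 copies with 5% of summits moved to a TSS did. For the gene lists, 2.5% of 200 random lists of 16 among 13968 genes passed 0.05. Of lists with coverage planted in a large share of their uncovered members, 96% passed. These p-values were not adjusted over lists, so the trial does not show the power for smaller effects after adjustment. For the 6-mers, 0 calls were made when summit and background windows were swapped at random, 100 of 100 6-mers planted in 5% of windows were recovered, and 91 of 100 planted in 2% were. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.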

Results

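H2.0 is a homeodomain transcription factor known from the visceral musculature of the fly embryo. ChIP-seq against its eGFP tag had been carried out in whole embryos aged 0 to 24 h. The control library was not used here, so peaks are sites of signal and were not shown to be bound by H2.0. The single group had 2 biological replicates, and no second condition or stage was compared. The pooled thresholded set held 4590 peaks, 4565 of them on the assembled arms of dm6, with a median width of 296 bp. By the deposited q-value, 3166 of the 4565 peaks on the arms (69.4%) were below 0.05, so the rest are in the set by their IDR only. All 4590 come from the ranked pooled list, whose component peaks were not identified as those of the 2 replicates. The IDR of the pooled set is therefore not taken here as agreement between the replicates. The list of replicate 1 held 3059 peaks and that of replicate 2 held 3124. The signal value of a peak, as the authors deposited it, ranged from 2.18 to 2069 in the pooled set with a median of 94.6, against a median of 18.99 in the ranked pooled list of 136802 peaks. Reads were not analysed here, so depth is unknown and values per peak carry no counting error.

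The first comparison asked which sites passed the threshold in each replicate's own list. The pooled set was split by signal into 4 classes of equal size. In the highest class, 1136 of 1142 peaks (99.5%) had a summit in both replicate lists. This share was 77.8% in the next class, 17.3% in the one after it and 2.28% in the lowest, where 65.2% of peaks were in neither list. Absence from a replicate list means that a peak missed that list's own threshold, not that it had no signal there. All 4369 peaks of the conservative list come from the ranked list of both replicates. That conservative list had a summit within 200 bp of 3866 of the 4565 pooled peaks (84.7%). Over the whole lists, 2248 of 3047 replicate 1 peaks on the arms (73.8%) had a replicate 2 summit within 200 bp, and 2253 of 3110 replicate 2 peaks (72.4%) had a replicate 1 summit. Circular shifts gave a mean of 28.4 shared replicate 1 peaks and at most 52 (permutation by shifts, two-sided p = 0.002, the smallest that 1000 shifts can give). Open chromatin alone lifts such an overlap above shifts, so this test does not show that the shared peaks are bound by H2.0. Over all 115617 ranked pairs, the Spearman correlation of the replicates' signal values was 0.310 and the SD of their log2 ratio was 1.05. The 2 lists compared within replicate 1 gave a correlation of 0.225 (84074 pairs) and those within replicate 2 gave 0.239 (89776 pairs). Each of these lists was taken to hold only part of the reads of 1 replicate, and the peaks paired differ. These values are therefore no like comparison with 0.310. Past the IDR threshold, which itself selects peaks for agreement, these 3 correlations were 0.768 (4361 peaks), 0.749 and 0.719. They are across peaks, which are not independent replicates.

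**Figure D1:**
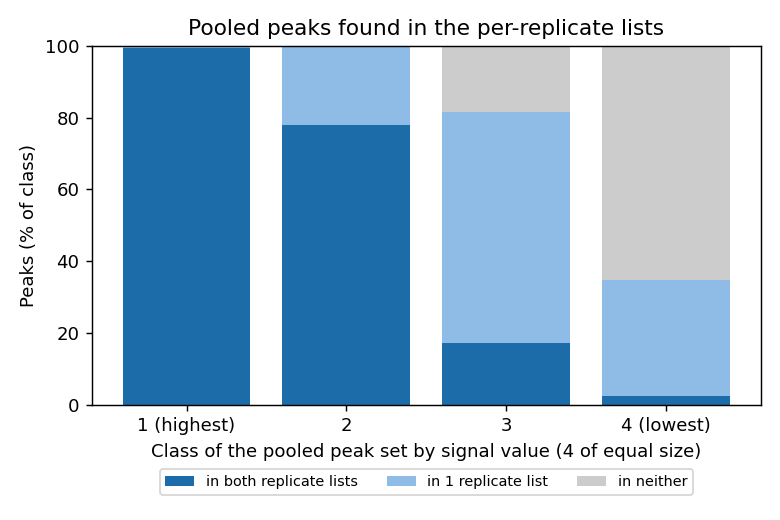
Share of pooled peaks (% of each class, vertical axis) found in both, 1 or neither of the per-replicate thresholded lists, by class of signal value (horizontal axis, 4 classes of equal size). Presence in both lists fell from 99.5% in the highest class to 2.28% in the lowest.

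The 25 strongest peaks present in both replicates lay mostly at promoters. Of these, 19 were promoter peaks, and the median distance from summit to nearest TSS was 128 bp. The highest was at CG14100 (FBgn0036889; arm 3L, 19590474 to 19590752), with a signal value of 2069, and 1069 and 1009.5 in the separate lists of replicates 1 and 2. Its summit lay in intergenic sequence 94 bp upstream of the TSS. The next stood 39 bp upstream of Ugalt (FBgn0024994; X, 2703741 to 2704036), which encodes a UDP-galactose transporter, at 1983, with 978 and 1009 in the replicates. The peak at mRpL41 (FBgn0034001; 2R, 15217611 to 15217900) reached 1881, with 922 and 961 in the replicates. The peak at mRpS10 (FBgn0038307; 3R, 15229400 to 15229663) reached 1420.4 and that at mRpL23 (FBgn0035335; 3L, 2373480 to 2373738), in the 5′ UTR, reached 1245. Among the others, ph-p, a Polycomb group gene, had an intronic summit at 1495, Chro a 5′ UTR summit at 1195, Adf1 an intronic summit at 1161 and Tlk, a kinase gene, an intronic summit at 1144. The other promoter peaks were at Tcs5, CenG1A, PNPase, CG5611, CG8320, asRNA:CR45928, px, CG9147, CG18549, CG7601, CG1888, gish and SLC5A11. The remaining peaks lay in introns of CG11050 and CG32772 and in intergenic sequence 11912 bp from CG13323. Over the 25 peaks, the SD of the log2 ratio of the replicates' signal values was 0.14.

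H2.0 itself (FBgn0001170; 2L, 6013059 to 6019402, minus strand) held 1 pooled peak. It spanned 6013784 to 6014079 with its summit at 6013932, in a coding exon 5470 bp downstream of the TSS, and had a signal value of 76.5, above 34.1% of the pooled set. The conservative list had the same peak and 2 more nearby, in coding exons of the neighbouring genes CG9098 (summit 6009505, signal value 61.9) and CG9107 (summit 6023732, 52.6). Neither thresholded replicate list had a summit in the gene. In the ranked lists of the replicates, the summit stood at 37.1 in replicate 1 (IDR 0.0111) and 38.1 in replicate 2 (IDR 0.0117), just short of the threshold of 0.01 in both. Coding exons held 1.29% of pooled summits and 20.2% of weak ranked peaks. Whether the peak in H2.0 reflects binding cannot be told here. Extra copies of the locus, carried with the tagged transgene, are not excluded.

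**Figure D2:**
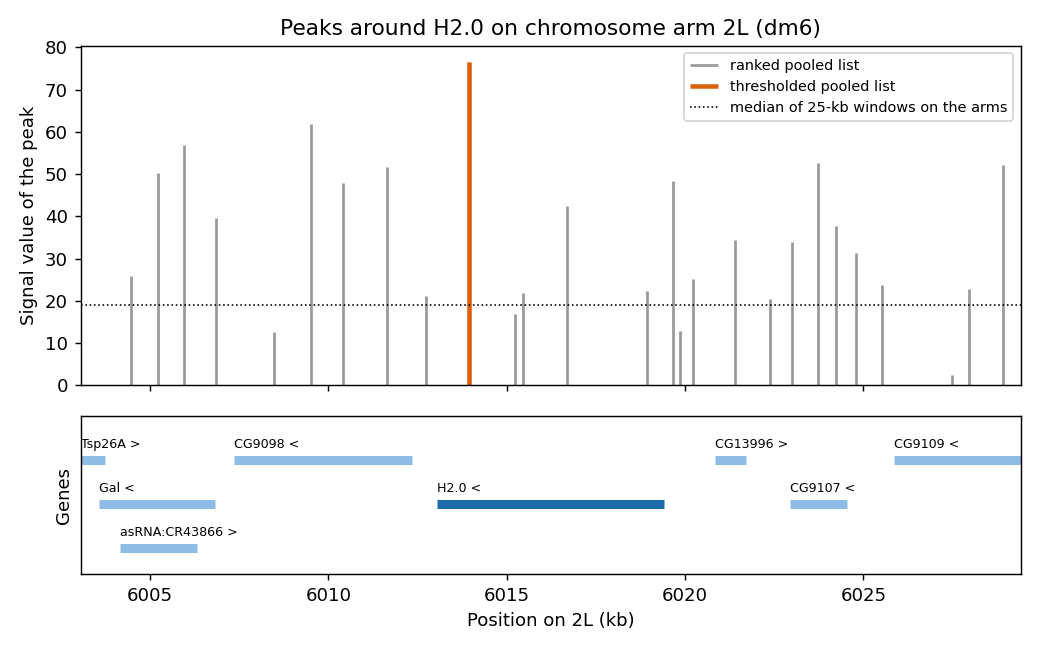
Peaks around H2.0 on arm 2L of dm6, with position in kb on the horizontal axis and the signal value of each peak on the vertical axis of the upper panel; grey lines are peaks of the ranked pooled list and the orange line is the pooled thresholded peak, and the dotted line is the median of 25-kb windows on the arms (19.1). The thresholded peak at 76.5 lies inside H2.0 among lower ranked peaks, and the lower panel shows annotated genes with arrowheads for strand.

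The position of the peaks relative to genes was compared next. Promoters held 2101 of 4565 summits (46.0%), against a mean of 13.5% in circular shifts, a 3.40-fold excess. The excess was present in each replicate, with 46.7% of summits in replicate 1 and 50.6% in replicate 2. Coding exons held 59 summits (1.29%, against 13.0% in shifts), 3′ UTRs 0.986% against 5.05%, and intergenic sequence 14.3% against 27.3%. The coding exon share was lower still in the separate lists, at 0.427% in replicate 1 and 0.354% in replicate 2. Introns held 36.0% against 39.5%, and 5′ UTRs outside promoters 0.372% against 0.784%. For promoters, introns, coding exons, 3′ UTRs and intergenic sequence the adjusted p was 0.0028, resting on the smallest p the shifts can give, and for 5′ UTRs it was 0.0047. Other exons did not pass (0.964% against 0.815%, adjusted permutation p = 0.33). The difference for introns ended in replicate 1 alone (0.943-fold, adjusted permutation p = 0.0793) and with weak ranked peaks in place of shifts (36.0% against 37.0%, adjusted p = 0.22).

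**Figure D3:**
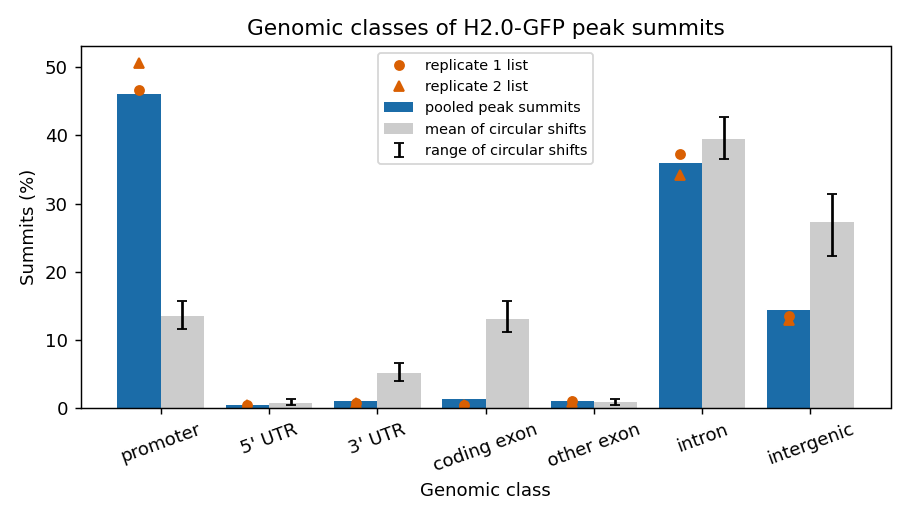
Share of summits (%, vertical axis) by genomic class (horizontal axis) in the pooled set (blue bars), the mean of 1000 circular shifts (grey bars, with error bars from lowest to highest shift), and the separate lists of replicates 1 and 2 (orange circles and triangles). Promoters held 46.0% of summits against 13.5% in shifts, and coding exons 1.29% against 13.0%.

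Promoter peaks were also the stronger ones. Their median signal value was 104 (quartiles 72.4 and 180.2), against 88.98 (66.0 and 137) for other peaks, a difference of 15.1 (permutation test, two-sided p = 1e-05, the smallest that 100000 resamples can give). The promoter share was 57.8% in the class of highest signal (95% exact binomial interval 54.9 to 60.7) and 38.5% (35.6 to 41.4) in the lowest. By arm, X held 887 summits, 1.14 times its share of assembled length, with 1.18 in replicate 1 and 1.12 in replicate 2. Arms 2L, 2R, 3L and 3R lay between 0.983 and 1.06 times their share. Chromosome 4, which is largely heterochromatic, held 5 summits (0.112 times its share, and 0.167 and 0.295 in replicates 1 and 2), and Y held 0.

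Gene groups were compared to see whether genes of the tissue in which H2.0 is known, or of other embryonic tissues, were covered more often than genes of like length. Among the 19 lists, ribosomal protein genes were the group that passed the test. A summit lay in the widened span of 62 of 85 of them (72.9%), against 17.1 expected from length-matched lists, a 3.62-fold excess (permutation p = 0.0002, the smallest possible here, adjusted p = 0.0038). The strongest were at RpS27 (470.3, summit 2 bp from the TSS), RpL7 (345, 26 bp) and RpL23A (303, 91 bp), while the peak counted for RpL31 (316) lay in an intron of the neighbouring gene clos, 1666 bp from the TSS of RpL31. Each of these 4 had summits in both replicate lists. Heat shock genes held summits in 9 of 18 members, against 4.35 expected (adjusted permutation p = 0.26), and among them were Hsp27 (572), Hsp83 (271) and Hsp26 (174), whose summit also served for Hsp67Ba. The list of other abundantly transcribed genes had 7 of 13 against 4.01 (adjusted permutation p = 0.64), among them Gapdh2 (782), Act5C (352), eEF1alpha1 (226) and Pgk (196). The proteasome list had 8 of 32 against 6.97, with Rpn5 (476), Rpn3 (232), Prosbeta6 (162) and Rpn6 (121).

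Genes of the visceral mesoderm, where H2.0 is known to be expressed, did not stand apart, with 8 of 16 members covered against 7.04 expected (adjusted permutation p = 0.95). H2.0 itself is a member of this list and was counted as covered through the peak described above. The strongest peak of this list lay 364 bp upstream of the T-box gene org-1 (FBgn0021767; 588, with 293 and 308 in the replicates). The cell adhesion gene kirre held 23 summits, the highest at 266, and jeb (194) and Fas3 (182) had intronic summits. Midgut patterning genes were covered in 12 of 20 cases against 10.1 expected (adjusted permutation p = 0.92). Their strongest peak, counted for Med (1000.5), lay in intergenic sequence 5125 bp from its TSS, followed by Mad (295), hth (257) and dpp (228). Fisher's exact test without matching for length passed for this list (adjusted p = 0.040), and the length-matched test did not. Early mesoderm genes had 9 of 16 against 7.80, with zfh1 (406), tin (381), ths (236) and how (199). Cardiac genes had 6 of 14 against 6.03, with tin, sli (194), Doc2 (150.3) and Doc1 (79.7).

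None of the remaining lists passed, with adjusted p of 0.64 or more. Muscle identity genes had 5 of 19 against 8.27 (kn 111, nau 107, Poxm 99.2, sd 61.4) and muscle structural genes 10 of 27 against 11.2 (Msp300 364, sls 281, Zasp52 140.3, Mlc2 137). Nervous system genes had 9 of 25 against 10.8 (elav 472, ChAT 146, fne 124, pros 106), and epidermis and cuticle genes 5 of 17 against 7.92 (grh 239, crb 232, pot 158, nyo 73.0). Hemocyte and fat body genes had 4 of 16 against 6.57 (ush 239, Lsp2 223, Hml 85.9, lz 57.1), endoderm and gut genes 2 of 11 against 4.76 (bowl 453, fkh 91.7), and trachea and salivary gland genes 5 of 12 against 4.50 (rib 187, trh 98.8, fkh, bnl 72.8). Hox genes had 4 of 8 against 4.45 (Abd-B 130.1, Antp 104, Dfd 73.4, pb 63.6), the NK homeobox cluster 1 of 7 against 2.68 (tin), segmentation genes 4 of 20 against 6.86 (inv 95.6, slp1 93.0, wg 71.5, ptc 51.5), and Notch target genes 6 of 13 against 3.98 (neur 278, N 270.4, E(spl)m3-HLH 184, E(spl)m8-HLH 96.7). Numbers after gene symbols are the highest signal value in the widened span, and that summit can belong to a neighbouring gene. Covered genes were longer than others (median span 3.80 against 1.85 kb), which is why lists were matched on length.

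**Figure D4:**
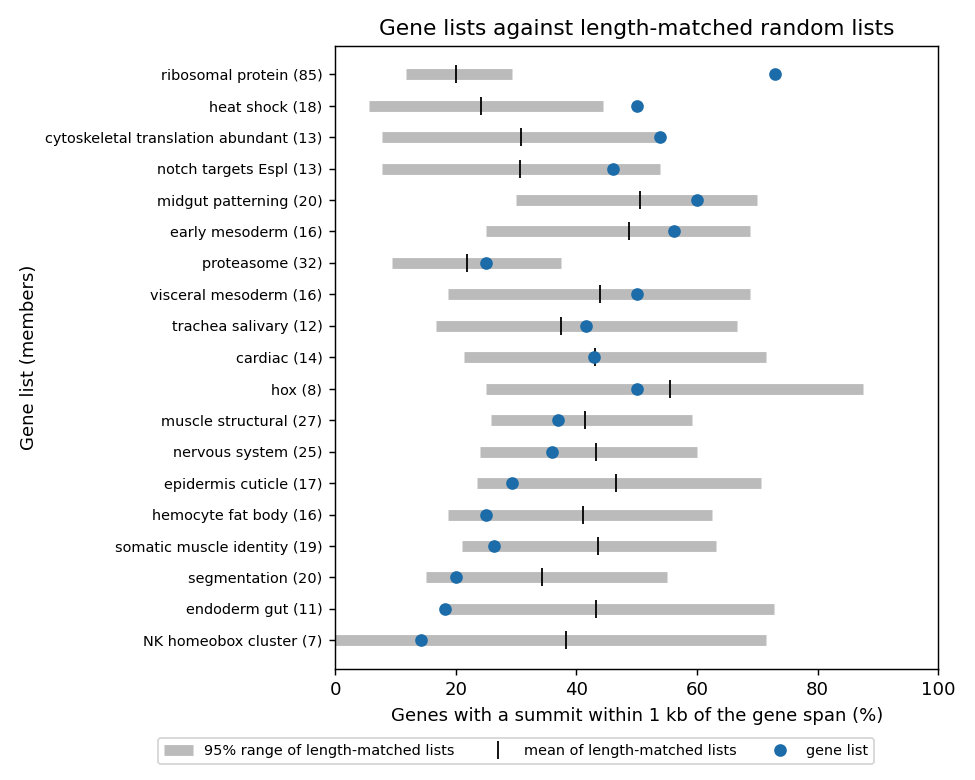
Share of each gene list with a summit within 1 kb of the gene span (%, horizontal axis; list and number of members on the vertical axis) as blue points, with the mean (black tick) and 95% range (grey bar) of 10000 length-matched random lists. Ribosomal protein genes, at 72.9%, lie beyond their range.

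The sequence at the summits was compared with flanks of the same peaks. The DRE, TATCGATA, the site of the promoter factor DREF, occurred at 1.71% of summits and 0.307% of flanks (odds 5.41, exact McNemar test, adjusted p = 1.05e-10). By the same exact test, the Mef2 motif had odds of 1.91 (adjusted p = 4.61e-10), the homeodomain core TAATTA 1.46 (9.24% against 6.55%, adjusted p = 5.14e-06), the caudal and Abd-B class homeodomain motif 1.44 (2.18e-09) and the GATA motif 1.37 (0.000163). A split by signal class was not among the planned tests. From the highest to the lowest of the 4 classes, the odds of Mef2 were 3.75, 2.41, 1.89 and 0.761, and those of TAATTA 2.11, 1.48, 1.46 and 0.921. The caudal and Abd-B class motif had 2.23, 1.44, 1.34 and 0.944. GATA differed, with 1.08, 1.90, 1.87 and 0.871, and did not pass in the highest class (exact test, adjusted p = 0.93). DRE occurred at 1.05%, 1.93%, 2.19% and 1.67% of summits in these classes, and in 4, 7, 2 and 1 flanks, and did not pass in the highest class (exact test, adjusted p = 0.19). Of the 78 summits with DRE, 69 were at promoters, and the list of replicate 1 had 35 such summits and that of replicate 2 had 74. Mef2 had odds of 3.07 in the list of replicate 1 and 2.16 in that of replicate 2, whose flanks were drawn anew, and 2.02 to 2.71 in 200 other draws of the flank side for the pooled set, all above the 1.91 of the first draw. Motifs less common at summits by the exact test were GAGA (odds 0.425, adjusted p = 1.52e-06), the E-box CANCTG (0.729, 1.86e-07), the Twist E-box (0.799, 0.0101), Su(H) (0.534, 0.0166) and Grainyhead (0.538, 0.0262). The last 3 did not pass in the list of either replicate alone (adjusted p of 0.18 or more). GATA did not pass in the list of replicate 2 alone (odds 1.24, exact test, adjusted p = 0.0606). Among the 200 other draws the Twist E-box passed in 59, Grainyhead in 74 and Su(H) in 180, while the other 7 motifs past the threshold passed in all 200. The NK-class homeodomain, forkhead, Zelda, TCF, AP-1, Scalloped and M1BP motifs did not pass, with odds from 0.802 to 1.97. Within 100 bp of summits, M1BP (2.95, 1.21e-05) and the NK-class motif (1.19, 0.049) did pass by the exact test. Summit windows held 35.4% GC and flanks 43.5%. Against random genome windows of the same GC content, DRE kept odds of 5.81 (exact test, adjusted p = 3.14e-11) and M1BP reached 3.0 (0.0145). TAATTA had 0.939 (0.69) there, Mef2 1.10 (0.66) and GATA 1.03 (0.92), while the caudal and Abd-B class motif was less common at summits (0.833, 0.00867).

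**Figure D5:**
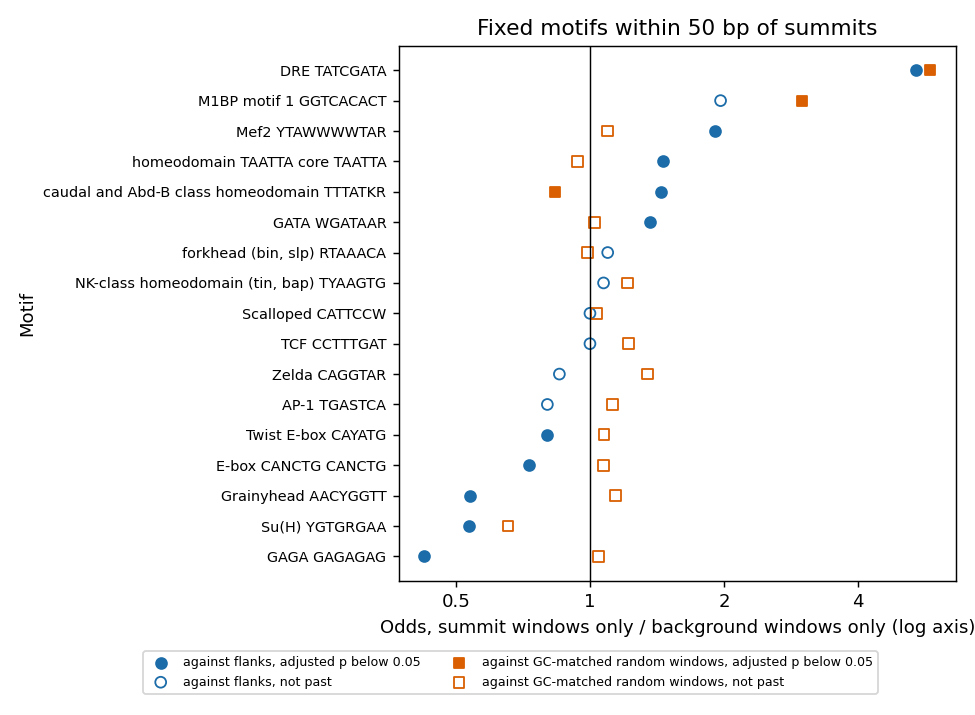
Odds of each fixed motif within 50 bp of summits (horizontal log axis; motif and its pattern on the vertical axis) against flanks (blue circles) and against random windows matched on GC content (orange squares), filled where the adjusted p is below 0.05. DRE lies at 5.41 and 5.81, and TAATTA at 1.46 and 0.939.

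Of all 6-mers, 453 were more common at summits than in flanks and 872 less common. The largest odds belonged to AT-rich 6-mers, namely TAGCTA (2.87), ATATTA (2.77), TATTAA (2.67), AATATA (2.62) and TTAAAA (2.58). The lowest were those of AGGAGG (0.205), CCCAGG (0.251), CCGGAG (0.253), GGAGGA (0.266) and ATCCGG (0.267). Their adjusted p was 3.05e-10 or lower by the exact test. Against GC-matched windows, 140 6-mers were more common and 99 less common, and the odds of TAGCTA were 1.47, of ATATTA 1.22 and of TTAAAA 1.39, while TATTAA and AATATA did not pass (1.16 and 1.09).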

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

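The tests on the H2.0 locus in this part were chosen only after its peaks had been seen. The pooled thresholded list holds 25 peaks on unplaced scaffolds, all of scaffolds assigned to X, which no comparison used; their highest signal value was 492. The ranked pooled list holds 141 peaks past the score minimum that the thresholded list leaves out, 72 of them on 3R and 31 on 2L. They include strong peaks inside ush near cbt (signal value 1716), in Lk6 (1395), in larp (964) and in trx (754), named after their values were seen. With those on the arms added back, the promoter excess was 3.39-fold and 1 gene list passed.

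Another pattern outside the main set lies around H2.0, in the signal of ranked peaks and not in their number. Within 25 kb (2L, 6003731 to 6028730), 25 ranked peaks below the threshold surround the thresholded one. This count is not unusual in a list of 134701 peaks on the arms. The 5-kb bins from 6005001 to 6015000 held 5 and 4 ranked peaks, and bins to either side held up to 10. The median signal value of the ranked peaks in the 25 kb, the thresholded peak included, was 32.6. Windows of this width had a median of 19.1, which put the block at percentile 99.7 of 24170 windows. The signal was uneven: of the 5-kb bins, those from 6005001 to 6015000 had medians of 50.3 and 49.8, above the 99th percentile of bins (44.6), while the bin with the TSS of H2.0 had 22.1, at percentile 67.9. The block lay above the median of windows in the ranked list of each replicate, at 19.5 against 12.6 in replicate 1 and 15.4 against 12.4 in replicate 2. It stood at percentile 99.4 in replicate 1 and 91.1 in replicate 2, so it was raised in both. How far replicate 1 carried the signal stays open. Extra copies of the locus in the strain, carried with the tagged transgene, cannot be told apart from other sources, since 1 of the 2 bins that overlap H2.0 is high and the other is not, each with 6 peaks or fewer. A biological explanation, binding spread over the locus, was not tested, and the extent of the transgene was not used here.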

How the results depend on the processing

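Of 66 values that answer a comparison under an alternative, 56 stayed the same, which means the same direction and side of the threshold for a tested value, within 1.5 times for a count, and inside the 95% interval of the main value for a share or correlation. Settings without shoulder peaks, with left-out ranked peaks, with other flank draws or with weak ranked peaks as background were chosen after seeing the data. The share of replicate 1 peaks shared was 72.1% within 100 bp, 75.4% within 500 bp, 65.8% by reciprocal overlap and 80.4% in the stronger part of each list. The promoter excess stayed between 2.41-fold and 5.47-fold. The replicate correlation was 0.768 past the IDR threshold and 0.274 away from promoters. In the stronger part by signal, 2 gene lists passed, heat shock genes (2.88-fold) being the second. The count of fixed motifs past the threshold was 6 without replicate 1 and 7 without replicate 2, and 3 against GC-matched windows, where 239 6-mers passed. Against GC-matched windows the odds of 6 of the 10 motifs past the threshold changed side: TAATTA 0.939, caudal and Abd-B class 0.833, Twist E-box 1.08, E-box CANCTG 1.07, GAGA 1.04 and Grainyhead 1.14. Those of forkhead (0.987), Zelda (1.35) and AP-1 (1.12), not past it in either, did too. That setting changes both the place of the background windows and their GC content, so these changes are not put down to base composition alone. The GATA call ended there (1.03, exact McNemar test, adjusted p = 0.92) and without replicate 1 (1.24, adjusted p = 0.0606). With another peak list or wider windows, the Grainyhead call ended in all 7 settings (odds 0.579 to 0.744), the Su(H) call in 5 of them (0.442 to 0.804) and the Twist E-box call in 5 (0.846 to 0.885), all with odds still below 1. Fewer windows do not account for every loss, since Grainyhead and the Twist E-box also ended with left-out ranked peaks (4686 windows) and Grainyhead and Su(H) with 100 bp windows (4565, as in the main set). The draw of the flank side matters too. Without shoulder peaks and with flanks drawn anew, forkhead passed (1.27, exact McNemar test, adjusted p = 0.0142) and Grainyhead and the Twist E-box did not; with each summit keeping its flank, forkhead did not pass (1.10, adjusted p = 0.41) and the other 2 did. Other flank draws gave 7 to 12 motifs and 1275 to 1373 6-mers past the threshold. On chromosome 4 the ratio was 0.295 without replicate 1. Leaving out a replicate gives no value for shared peaks or replicate correlation, which need both. Read depth is unknown, so its limit on weak peaks could not be given.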

Other observations

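All tests in this part were chosen only after the results had been seen. Of 7 gene classes, 3 held a summit within 500 bp more often than in circular shifts (two-sided permutation p = 0.002 and adjusted p = 0.0047 for each). Protein-coding genes had 3531 of 13968 (25.3%) against a mean of 2060, non-coding RNA genes 349 of 3289 (10.6%) against 207, and small nuclear RNA genes, which encode spliceosomal and related RNAs, 7 of 32 (21.9%) against 1.20. The small nuclear RNA genes were snRNA:U5:35D (signal value 123), snRNA:U1:95Ca (103), snRNA:U6:96Ab and snRNA:U6:96Ac, which share a summit (93.8), snRNA:U5:63BC (93.4), snRNA:U2:34ABb (69.2) and snRNA:7SKa (63.6). Transfer RNA genes had 17 of 290 against 9.94 (adjusted permutation p = 0.21), small nucleolar RNA genes 11 of 269 against 9.75, pseudogenes 8 of 330 against 15.9 (adjusted permutation p = 0.13) and ribosomal RNA genes 0 of 99 against 3.57.

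Some genes held many summits. Of the 22 genes with 8 or more, 12 were on X. The most were in kirre (23 in 394 kb), CG1677 (17 in 125 kb), CHES-1-like (13 in 27.0 kb) and sbb (12 in 79.1 kb). These genes were picked by their counts, so no test was made for single genes. Shifts gave a mean of 38.7 genes with 8 or more, above the 22 observed in every shift (lowest 24, permutation p = 0.002, the smallest possible).

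Against GC-matched windows, the 6-mers with the largest odds were GGCGCC (3.17), CGATAG (3.03), ACAGTG (2.70), ACACTG (2.65) and GCGCCA (2.21). ACAGTG occurred at 8.50% of summits and 3.37% of matched windows (exact McNemar test, adjusted p = 1.27e-22).

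The replicates differed in the peaks that each had alone. Of 799 peaks in the replicate 1 list alone 35.8% were at promoters, and of 857 in the replicate 2 list alone 50.1% were (Fisher's exact test, p = 4.59e-09). Their mean summit GC content was 33.6% and 40.1%, a difference of 6.49 points (permutation test, p = 1e-05, the smallest possible). A difference tied to GC content was not confined to these peaks. Over 4361 peaks past the IDR threshold, the log ratio of the replicates' signal values had a Spearman correlation of -0.268 with summit GC content. Its sign depends on the column order, which was not assigned. Replicate contrasts in promoter share and motifs were not adjusted for this. Shoulder peaks numbered 92 in the pooled set, with a median signal value of 9.97, and 94.6% of them lay within 500 bp of another peak.

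Summits were AT-rich on average, and mean GC content was lower in the classes of higher signal. It was 31.5% in the highest of 4 signal classes and 40.8% in the lowest, with flanks at 44.2% and 42.3%, and across peaks the Spearman correlation of signal and GC content was -0.332. In the lowest class 54.5% of summits were below their flanks. The 59 summits in coding exons held 59.0% GC, 17.7 points above their flanks, and those in 3′ UTRs (45) and 5′ UTRs (17) were 4.91 and 3.79 points above. Only 5 of the coding exon summits were in the stronger part of the pooled set by signal. The lists of replicates 1 and 2 held 13 and 11 such summits. A drop in GC content alone does not place the peaks. Of sites with a drop in GC content like that of the strongest summits, 989 of 10072 at promoters (9.82%) and 864 of 51713 elsewhere (1.67%) had a summit within 200 bp, a ratio of 5.88 (4.28 to 6.98 on the large arms), while their mean GC content was 24.2% and 24.7%. Other features of base composition were not compared between these sites, so they are not excluded. Promoter composition does not account for the lower GC content at summits, as summits away from promoters also differed from their flanks by -7.39 points. The homeodomain core TAATTA was not more common than in windows of the same GC content (odds 0.939). A preference for AT-rich sequence in open chromatin, biological or from the library preparation, remains open and may not be separable with peak lists alone.

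Ribosomal protein genes were covered beyond their length-matched lists. Of the 62 covered genes, 55 (88.7%) had a summit within 200 bp of a TSS of their own, and the median distance over the 62 was 46 bp. Summits far from the genes' own start sites therefore do not account for the coverage. Promoters that neighbouring genes have close to these start sites are not excluded, because distances to the TSSs of neighbours were not compared. Signal raised at any abundantly transcribed gene cannot be told apart from binding of H2.0, because the list of other such genes has 13 members and the 95% exact binomial interval of its share (25.1% to 80.8%) includes the 72.9% of ribosomal protein genes. The control library was not used here and no biological explanation was tested, so either may be the source.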
